A study of Homo sapiens with 3 samples.

How the data were processed

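Gene expression was measured by 5′-selective RNA sequencing in 3 libraries of 1 group, HEK293 cells. Per the labels' protocols, 1000 cells were lysed with spiked control RNA (ERCC mix 1, 20000 molecules per cell), RNA was reverse transcribed from an oligo(dT) primer with a template-switching oligonucleotide that carries random bases, and a part of the reaction equal to 100 cells was amplified for 18 PCR cycles. The products were cut with the Tn5 transposase, the 5′ terminal fragments were captured on streptavidin beads, and the libraries were sequenced on a NextSeq 500. The random bases serve as unique molecular identifiers. The series' design text gives them as 4 N and 4 H bases, while the protocol's oligonucleotide has 6 N and 4 H bases.

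The authors deposited a table of raw counts per gene for the 3 libraries, with no normalization, as whole numbers whose totals differ between libraries. Per the submitters' processing notes, cutadapt 1.2.1 and STAR 2.4.0a were used with the build hg19 (GRCh37). The counting tool, the gene annotation, the use of strand and how identifiers were collapsed are not given in the sources used here, so the counts may be of reads or of molecules. The highest count of any row was 11390. The table has 17675 rows, 17595 of genes and 80 of spikes, and each row has at least 1 count, so no upper limit can be given for a gene that is not listed. Counts of antisense genes, overlapping genes and near-identical copies depend on counting rules that are not known here. Columns carry an index but no replicate number, and all 3 were used as unnumbered replicates of the group. Total counts were 1532672, 1384172 and 1601555 for libraries 20, 21 and 23, and endogenous counts without spikes 1475769, 1330877 and 1545594. A gene at 10 CPM thus rests on few counts per library, and intervals and p-values of the exact test cover counting error only.

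Levels were computed as counts per 1000000 endogenous counts (CPM), with mean and SD over the 3 libraries. Before the data were examined, the tests, the alternatives, 28 gene lists, 57 contrasts and the ladder of spike amounts were fixed; the ladder, in steps of 2, was written from general knowledge of the product. Gene names follow the table, and 2 list members were found there under older names with the help of a RefSeq gene table. Each list was described by its share of counts and by the median CPM over all members, with 0 for members not listed. The percentile of that median was taken among 10000 random lists of the same size. Random lists were drawn from listed genes only, so unlisted members lower the percentile of a list.

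Contrasts between genes or lists were taken per library as the log2 ratio of summed counts with a pseudocount of 0.5 per side, and tested with limma's moderated one-sample test with Benjamini-Hochberg adjustment over 43 contrasts, at 0.05. The other 14 had a side that is not listed in the table. Differences between libraries were tested per gene and pair with a 2-sided exact binomial test conditional on the endogenous totals, for genes with at least 10 pooled counts, with Benjamini-Hochberg adjustment over all genes and the 3 pairs at 0.05; this compares libraries, not conditions. The common coefficient of biological variation came from edgeR with an intercept-only design, TMM factors and filterByExpr. The spike response was the least-squares slope of log2(count + 0.5) on the log2 nominal amount. Molecules per cell were endogenous over spike counts times the spike molecules per cell.

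The named genes follow a rule fixed with the tests: the 25 most abundant genes, the 5 with the lowest adjusted p between libraries, up to 4 members of each list with the highest CPM, both genes of each contrast given, and the 3 most counted spikes. Some genes that the rule names are not reported here. MALAT1, CLSPN, RNA28S5 and most HOX genes fall outside it and were chosen after their values were seen. GC content and overlap of genes were taken by name from the GENCODE v29 annotation of GRCh38, which is not the authors' build, and no coordinates were used. GC content was known for 99.0% of genes above 100 counts.

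The scripts were tested on simulated counts. The pair test recovered 43.5% of 200 genes changed 1.5-fold and 93.0% of 200 changed 2-fold, all with at least 100 pooled counts, and called 8 and 12 unchanged genes; with no change it called 0. The contrast test recovered 21 of 22 simulated 2-fold ratios and called 0 of 21 null ratios. For a simulated coefficient of variation of 0.1 edgeR returned 0.098, and for 0.2 it returned 0.195. Alternatives covered the minimum count, thinning, normalization (TMM, median-of-ratios, spikes), the dispersion tool (DESeq2), filters, pseudocounts, list medians in place of sums, lists without their most counted member, a chi-square test, spike subsets and leaving out each library. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, and in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.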

Results

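RNA 5′ ends of HEK293 cells were counted per gene in 3 libraries, each made from 1000 lysed cells with a share equal to 100 cells carried into PCR. HEK293 is an established human cell line from embryonic kidney that carries part of the adenovirus type 5 genome. In this method a template-switching oligonucleotide is added when reverse transcription reaches the 5′ end of an RNA. Tags are thus counted at 5′ ends, and whether longer transcripts gave fewer of them was not tested. Such a bias would enter the comparisons between genes. The 3 libraries form 1 group and are named here by the index in their column heading, 20, 21 and 23, because no label ties a column to a numbered replicate. No groups could be compared, and the comparisons below are between genes within a library and between libraries of the same cells. Nothing in the labels says whether the libraries came from separate cultures, so limma p-values measure only the spread between these samples, which may be technical. The p-values of the exact test between libraries cover counting error only. Total counts were 1532672 in library 20, 1384172 in library 21 and 1601555 in library 23. The spiked control RNAs took 3.69% ± 0.18 of them (SD, n = 3 libraries). Levels below are counts per 1000000 endogenous counts (CPM) as mean ± SD over the 3 libraries, and at these depths 1 count equals 0.647 to 0.751 CPM.

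Transcripts for ribosomal proteins, mitochondrially encoded subunits and general growth proteins were the most abundant RNAs. The 25 most abundant genes took 10.6% ± 0.30 of endogenous counts (SD, n = 3), and 18 of them encode cytosolic ribosomal proteins. MT-CO2, a subunit of cytochrome c oxidase encoded by the mitochondrial genome, stood first at 6148 ± 241 CPM. It was followed by RPL31 at 5127 ± 113 CPM and by NPM1, a nucleolar chaperone of ribosome assembly, at 5077 ± 268 CPM. RPLP1 reached 4969 ± 92.7 CPM, and the mitochondrially encoded MT-ATP8 and MT-CYB reached 4909 ± 335 and 4729 ± 235 CPM. The glycolytic enzyme gene GAPDH had 3811 ± 127 CPM, MIF, which encodes a cytokine with tautomerase activity, had 3607 ± 116 CPM, and the prothymosin gene PTMA had 3513 ± 299 CPM. The other ribosomal protein genes among the 25 lay between RPL23A at 4643 ± 129 CPM and RPL41 at 3452 ± 32.1 CPM. Ribosomal protein genes have many processed pseudogenes, and MT-ATP8 overlaps MT-ATP6, so the split of reads among such copies is uncertain. Of 17595 endogenous genes with a count in any library, 12781 had a count in all 3. The libraries detected 14979 ± 248 genes each (SD, n = 3), 7850 genes averaged at least 10 CPM, 1743 at least 100 CPM and 158 at least 1000 CPM. The 361 most abundant genes made up 50% of the counts.

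The protein synthesis machinery dominated the counts. All 79 genes of the cytosolic ribosomal protein list had counts, and together they took 21.2% ± 0.20 of endogenous counts with a list median of 2807 ± 15.9 CPM (SD, n = 3). The 76 genes for proteins of the mitochondrial ribosome took 1.82% ± 0.039, with a median of 206 ± 2.86 CPM; MRPL3 (663 ± 43.2 CPM) and MRPS21 (662 ± 12.3 CPM) were the most abundant. In a library the cytosolic set outweighed the mitochondrial set by a log2 ratio of 3.54 ± 0.024, an 11.6-fold excess (limma adjusted p = 1.9e-05, higher in 3 of 3 libraries). Translation factors took 1.99% ± 0.013 of the counts. Their leading members were NACA and BTF3, the subunits of the nascent polypeptide-associated complex, at 2161 ± 13.9 and 1488 ± 10.6 CPM, the elongation factor gene EEF1A1 at 1572 ± 136 CPM and EIF5A at 1261 ± 36.3 CPM. The ribosomal proteins outweighed the translation factors by a log2 ratio of 3.41 ± 0.022 (limma adjusted p = 1.9e-05). This is a ratio of sums over lists of 79 and 37 genes, not a ratio per gene. The list medians were 2807 ± 15.9 and 343 ± 7.97 CPM. In the 3 pairs of ribosomal protein paralogs tested, the ubiquitous form led in each library. RPL39 exceeded RPL39L by a log2 ratio of 5.23 ± 0.088, RPS27 exceeded RPS27L by 3.95 ± 0.081 and RPL22 exceeded RPL22L1 by 2.73 ± 0.031 (limma adjusted p between 1.9e-05 and 2.4e-05). EEF1A1 likewise exceeded EEF1A2, the form of muscle and neurons, by 6.12 ± 0.55 (limma adjusted p = 0.00025).

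Genes of oxidative phosphorylation took more counts than those of glycolysis. The nuclear-encoded respiratory chain list took 4.14% ± 0.054 of endogenous counts (SD, n = 3), led by COX7C at 1708 ± 28.0 CPM, UQCRH at 1417 ± 21.1 CPM, ATP5G3 at 1330 ± 79.0 CPM and UQCR10 at 1285 ± 30.3 CPM. The 13 proteins encoded by the mitochondrial genome took 3.48% ± 0.16 and the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 took 0.488% ± 0.019. Glycolytic enzymes took 1.46% ± 0.037, below the nuclear respiratory chain list by a log2 ratio of -1.50 ± 0.037 (limma adjusted p = 8.0e-05, lower in 3 of 3 libraries). The respiratory chain list holds 75 genes and the glycolytic list 18, so this ratio of sums is not a ratio per gene, and the list medians were 498 ± 3.87 and 217 ± 13.9 CPM. The nuclear respiratory chain list exceeded the mitochondrially encoded proteins in summed counts by a log2 ratio of 0.25 ± 0.087 (limma adjusted p = 0.018), a call lost when any of the 3 libraries was left out (0.053 to 0.065). By list medians the order turned, with a log2 ratio of -2.37 (limma adjusted p = 7.6e-05). Within glycolysis, ENO1 at 2178 ± 38.3 CPM, LDHB at 2111 ± 35.2 CPM and TPI1 at 1884 ± 106 CPM came after GAPDH. The housekeeping isoforms exceeded the neuronal ones, by a log2 ratio of 7.34 ± 0.21 for ENO1 over ENO2 and 7.02 ± 0.28 for ALDOA over ALDOC (limma adjusted p = 2.4e-05 and 4.1e-05). Of the lactate dehydrogenase genes LDHB led, with LDHA over LDHB at -0.48 ± 0.023 (limma adjusted p = 0.0012), and HK1 exceeded HK2 by 0.59 ± 0.072 (limma adjusted p = 0.0015). PFKL and PFKP did not differ past the threshold (log2 ratio 0.03 ± 0.36, limma adjusted p = 0.87). The ADP/ATP carrier of dividing cells, SLC25A5, exceeded SLC25A6 by 5.27-fold and the muscle and heart form SLC25A4 by 14.4-fold (limma adjusted p = 0.00013 and 2.7e-05).

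**Figure D1:**
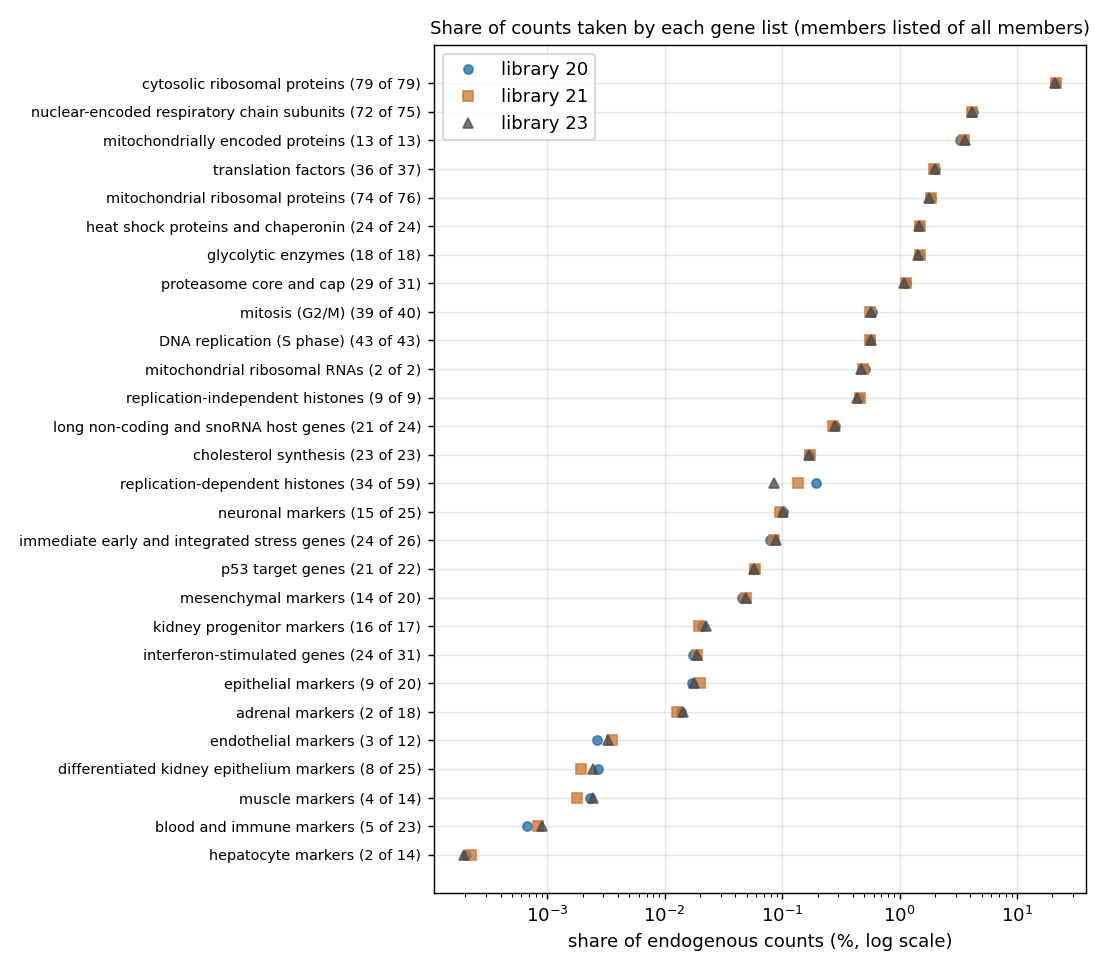
Share of endogenous counts taken by each of 28 gene lists (x axis, percent, log scale), with 1 point per library, and beside each name the members listed in the table out of all members. The cytosolic ribosomal proteins took 21.2% on average and the hepatocyte markers the smallest share. The replication-dependent histones, most of whose counts were of HIST1H4C, had the widest spread relative to their mean among lists above 0.1%.

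Genes of both DNA replication and mitosis were detected in each library. All 43 genes of the DNA replication list averaged at least 10 CPM, with a list median of 110 ± 5.01 CPM (SD, n = 3). They were led by MCM7, a subunit of the replicative helicase, at 341 ± 4.41 CPM and PCNA, the sliding clamp, at 338 ± 19.5 CPM, followed by the single-strand binding proteins RPA2 (323 ± 15.6 CPM) and RPA3 (313 ± 6.61 CPM). Of 40 mitosis genes 39 were listed, with a median of 72.9 ± 4.27 CPM, led by BUB3 at 539 ± 24.1 CPM, CKS2 at 505 ± 5.93 CPM, UBE2C at 485 ± 30.1 CPM and the cyclin gene CCNB1 at 365 ± 0.71 CPM. The summed counts of both lists did not differ past the threshold (log2 ratio -0.02 ± 0.029, limma adjusted p = 0.60), whereas by list medians the replication list was higher by 0.60 (limma adjusted p = 0.0015). CCNB1 exceeded the G1/S cyclin gene CCNE1 by 4.22 ± 0.20 and CDK4 exceeded CDK6 by 3.40 ± 0.091 (limma adjusted p = 6.8e-05 and 2.7e-05). CCND1 lay below CCND3 by a log2 ratio of -0.63 ± 0.17 (limma adjusted p = 0.0054) and did not differ past the threshold from CCND2 (-0.07 ± 0.30, limma adjusted p = 0.68). Without library 23, CCND1 was below CCND2 by -0.25 (limma adjusted p = 0.042). The inhibitor gene CDKN1B lay below CDKN1A by -0.55 ± 0.23 (limma adjusted p = 0.017), a call lost without library 23 (limma adjusted p = 0.069).

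Chromatin genes split by the kind of histone. Replication-independent histones took 0.446% ± 0.015 of endogenous counts (SD, n = 3), and most of this was H2AFZ at 2529 ± 123 CPM, with H3F3B at 687 ± 35.5 CPM, H3F3A at 636 ± 47.5 CPM and H2AFV at 240 ± 9.35 CPM. The replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, took 0.138% ± 0.055. HIST1H4C made up most of that share at 1206 ± 548 CPM, followed by HIST1H2BK at 81.7 ± 7.86 CPM. The replication-independent set was higher by a log2 ratio of 1.77 ± 0.56 (limma adjusted p = 0.0075). In a check chosen after the data were seen, the ratio without H2AFZ was 0.56 (limma adjusted p = 0.15), and without H2AFZ and HIST1H4C it was 3.44 (limma adjusted p = 1.9e-05). Near-identical histone copies make the split among single histone genes uncertain. H3F3B and H3F3A, which encode the same protein, did not differ past the threshold (0.11 ± 0.11, limma adjusted p = 0.17). HMGB1 exceeded HMGB2 by 1.73 ± 0.090, HMGA1 exceeded HMGA2 by 2.45 ± 0.14, and the maintenance methyltransferase gene DNMT1 exceeded DNMT3B by 2.49 ± 0.64 (limma adjusted p = 0.00012, 0.00012 and 0.0041).

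Chaperone and proteasome genes were abundant, and interferon-stimulated genes were low. Against random lists of the same size, the list median stood at the 85.6th percentile for immediate early and integrated stress genes, the 92.4th for p53 targets and the 0.185th for interferon-stimulated genes. Chaperone genes took 1.47% ± 0.013 of endogenous counts (SD, n = 3), led by the constitutive HSPA8 at 2131 ± 71.9 CPM, HSP90AA1 at 1564 ± 17.7 CPM, the mitochondrial chaperonin gene HSPD1 at 1408 ± 42.1 CPM and HSP90AB1 at 1188 ± 35.9 CPM. The stress-inducible HSPA1A had only 3 counts in all libraries together, though it has a near-identical neighbour that shares its reads. HSP90AB1 lay below HSP90AA1 by a log2 ratio of -0.40 ± 0.032 (limma adjusted p = 0.0021). Proteasome genes took 1.12% ± 0.028, with PSMA7 at 798 ± 8.10 CPM, PSMB1 at 791 ± 50.7 CPM, PSMB3 at 720.5 ± 51.2 CPM and PSMB5 at 697 ± 14.5 CPM. Immediate early and integrated stress genes took 0.0843% ± 0.0052, most of it from ATF4 (337 ± 30.1 CPM) and MYC (173 ± 1.47 CPM), while ASNS had 80.6 ± 5.38 CPM and DDIT4 32.2 ± 4.42 CPM. The chaperones exceeded this list by a log2 ratio of 4.13 ± 0.098 (limma adjusted p = 2.4e-05). Targets of p53 took 0.0582% ± 0.00050, with CCNG1 at 164 ± 8.72 CPM, PMAIP1 at 126 ± 6.79 CPM, C12orf5 at 46.1 ± 6.37 CPM and AEN at 29.04 ± 1.82 CPM, and CDKN1A was at 20.8 ± 3.25 CPM. They exceeded the interferon-stimulated genes by 1.66 ± 0.069 (limma adjusted p = 9.8e-05). Of 31 interferon-stimulated genes 5 averaged at least 10 CPM, and the list took 0.0184% ± 0.00094, led by IFITM2 at 57.2 ± 7.22 CPM, IFITM1 at 32.2 ± 1.72 CPM and IFI6 at 12.7 ± 4.64 CPM. Cholesterol synthesis genes took 0.170% ± 0.0026 and 21 of 23 averaged at least 10 CPM, with FDFT1 at 260 ± 5.55 CPM, FDPS at 187 ± 9.22 CPM, EBP at 179 ± 10.7 CPM and ACAT2 at 170 ± 3.03 CPM. Long non-coding and small nucleolar RNA host genes took 0.278% ± 0.0080, led by SNHG5 at 492 ± 36.8 CPM, SNHG16 at 398 ± 11.3 CPM, SNHG8 at 374 ± 13.9 CPM and ZFAS1 at 275 ± 18.8 CPM.

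Genes that mark differentiated cell types were mostly near the level of 1 count or not listed in the table, although most of these lists held single members well above it, as given below. Of the 28 lists, 14 had a median at or above the 99.9th percentile of random lists of the same size and 10 lay below the 2.5th, or 2 when only listed members entered. The 25 neuronal markers took 0.0998% ± 0.0029 of endogenous counts (SD, n = 3). Most of this came from STMN1, a microtubule regulator of dividing cells as well, at 623 ± 16.5 CPM and UCHL1 at 261 ± 8.03 CPM, and the neurofilament genes NEFM and NEFL had 35.6 ± 5.08 and 33.9 ± 9.07 CPM. Only 15 of the 25 markers were listed, and the list median was 0.442 ± 0.38 CPM. The neuronal list exceeded the differentiated kidney epithelium list by a log2 ratio of 5.39 ± 0.20 and the adrenal list by 2.87 ± 0.050 (limma adjusted p = 3.9e-05 and 2.4e-05). By list medians both ratios were 0.81 (limma adjusted p = 0.096), but the medians of the kidney epithelium and adrenal lists were 0 CPM in every library. That value is set by the neuronal median and the pseudocount, so it does not bear on either ratio. The adrenal share of 0.0136% ± 0.00085 was almost entirely FDX1, a mitochondrial ferredoxin, at 136 ± 8.43 CPM, and PNMT, the other listed member, had 1 count. Kidney progenitor genes took 0.0210% ± 0.0014, with CITED1 at 51.0 ± 5.22 CPM, HOXA11 at 26.9 ± 5.29 CPM and HOXD11 at 23.7 ± 3.58 CPM. Genes of differentiated kidney epithelium took 0.00237% ± 0.00039, from PODXL at 10.96 ± 1.73 CPM and LRP2 at 9.36 ± 2.02 CPM, and ATP6V1B1 and SLC5A2 stayed below 1 CPM on average. The progenitor list was higher by a log2 ratio of 3.14 ± 0.20 (limma adjusted p = 0.00012, higher in 3 of 3 libraries). Mesenchymal markers took 0.0481% ± 0.0019, led by VIM at 340 ± 23.4 CPM, CDH2 at 47.4 ± 10.1 CPM, SPARC at 35.3 ± 5.05 CPM and SNAI2 at 14.4 ± 1.66 CPM. Epithelial markers took 0.0183% ± 0.0014, with KRT18 at 97.55 ± 17.0 CPM, DSP at 48.6 ± 4.49 CPM, KRT8 at 21.1 ± 2.49 CPM and OCLN at 13.3 ± 1.13 CPM. The mesenchymal list was higher by 1.39 ± 0.078, and VIM exceeded KRT18 by 1.81 ± 0.19 (limma adjusted p = 0.00015 and 0.00046). In a check chosen after the data were seen, VIM carried the list ratio, which turned to -0.38 without VIM (limma adjusted p = 0.027) and was 0.71 without VIM and KRT18 (limma adjusted p = 0.00088). Blood and immune markers took 0.000803% ± 0.00012 and 0 of 23 averaged 10 CPM. Endothelial markers took 0.00316% ± 0.00046, nearly all from EGFL7 at 29.7 ± 5.33 CPM. Muscle markers took 0.00219% ± 0.00034, from TNNT1 at 20.98 ± 3.23 CPM, and hepatocyte markers 0.000208% from APOA1 and CYP2E1.

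**Figure D2:**
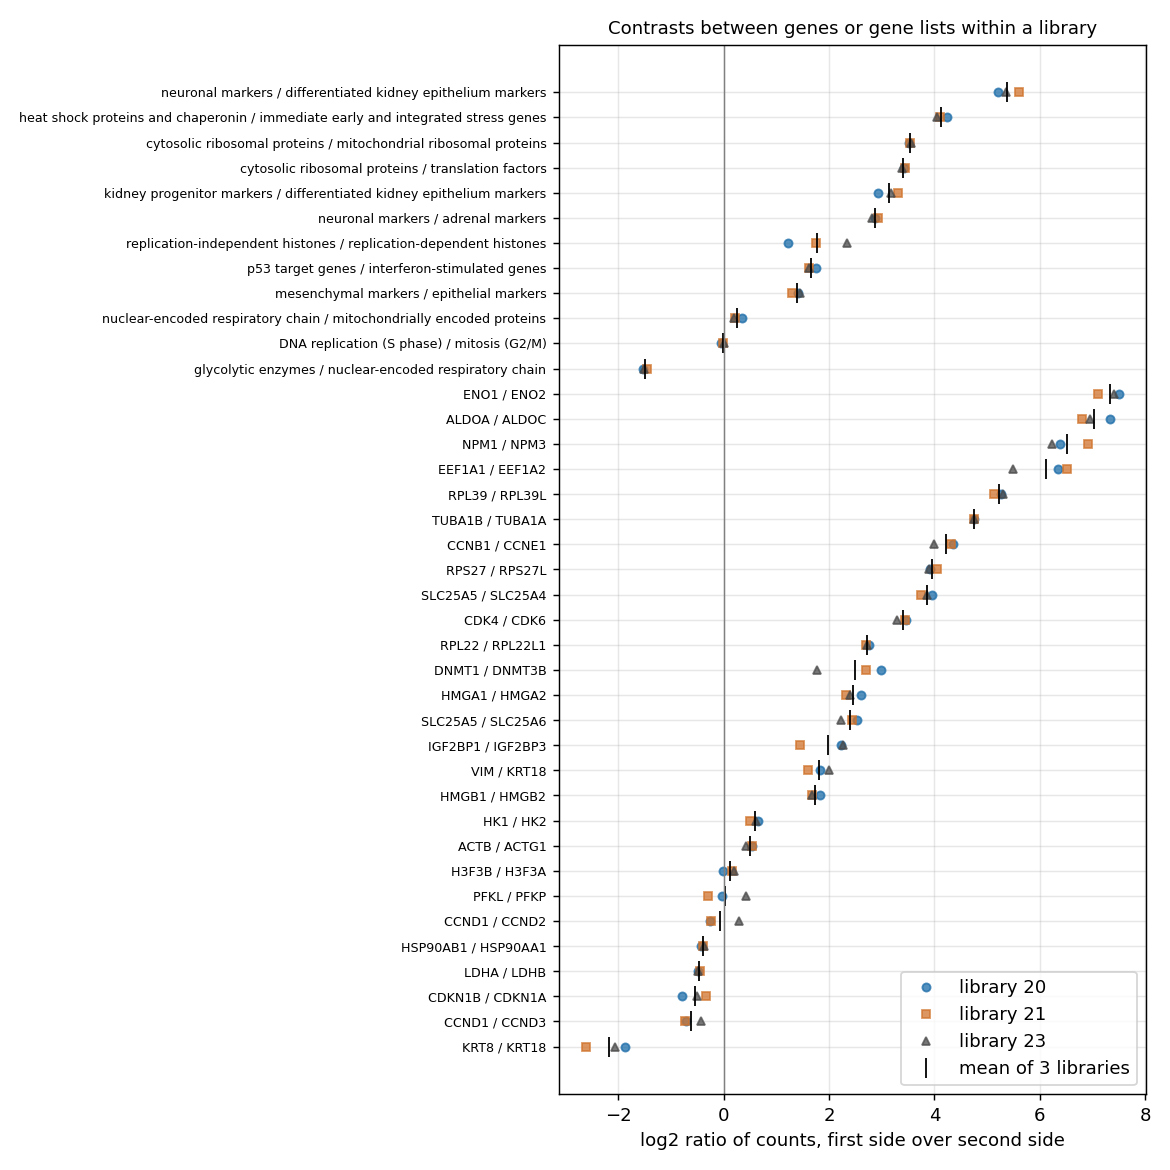
Log2 ratio of counts between genes or gene lists within a library (x axis, first side over second side), for the 39 contrasts with at least 10 pooled counts on each side. Points are the 3 libraries and bars their mean; ratios run from -2.19 for KRT8 over KRT18 to 7.34 for ENO1 over ENO2, and those of DNMT1 over DNMT3B, of the histone lists and of EEF1A1 over EEF1A2 spread most among libraries.

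Of 43 contrasts tested, 33 were higher on the first side, 6 on the second and 4 did not pass the threshold (limma moderated test on the per-library log2 ratio, Benjamini-Hochberg adjusted). Others among the 33 were TUBA1B over TUBA1A (4.75 ± 0.0024), NPM1 over NPM3 (6.51 ± 0.36), ACTB over ACTG1 (0.50 ± 0.072) and IGF2BP1 over IGF2BP3 (1.98 ± 0.46). Among the 6 was KRT8 over KRT18 at -2.19 ± 0.39 (limma adjusted p = 0.0016). The anti-apoptotic gene MCL1 had 37.7 ± 4.09 CPM and BCL2L1 8.60 ± 2.36 CPM, against 5 counts for BCL2 in all libraries together. These ratios compare counts, and capture differs between RNAs. Among 24 spiked RNAs of known nominal amount, the log2 of counts per molecule of single RNAs had an SD of 0.59. Of the 39 contrasts past the threshold, 5 had a log2 ratio smaller in size than that. They were LDHA over LDHB, HSP90AB1 over HSP90AA1, ACTB over ACTG1, CDKN1B over CDKN1A and the nuclear respiratory chain over the mitochondrially encoded list. A ratio of single genes carries the capture differences of both, so further gene ratios may lie within such differences.

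Libraries of the same cells differed in few genes. Between at least 1 pair of libraries 60 of 11424 genes differed beyond counting error (0.525%, exact binomial test per gene and pair, 2-sided, Benjamini-Hochberg over all genes and pairs), and 11 of them are transcribed from the mitochondrial genome. The lowest adjusted p belonged to the histone gene HIST1H4C, with 1761 CPM in library 20, 1191 in library 21 and 666 in library 23 (log2 ratio of 23 to 20 -1.40, exact adjusted p = 5.8e-166). The mitochondrially encoded MT-CO3, MT-ATP6, MT-ND2 and MT-ND4 were higher in library 23 than in library 20, by 0.68, 0.67, 0.75 and 0.46 on the log2 scale (exact adjusted p = 1.2e-66, 1.6e-62, 8.2e-57 and 3.4e-48). MT-ND4L, which overlaps MT-ND4, and MT-ATP8, which overlaps MT-ATP6, went the other way, by -0.29 and -0.13 (exact adjusted p = 3.9e-19 and 8.5e-05), and reads in these overlaps cannot be assigned with certainty. On the spike scale the MT-ATP8 difference was lost (-0.04, exact adjusted p = 0.72). The 13 mitochondrially encoded proteins held 10 genes past the threshold, and 11 when adjusted over the list alone. Among 78 tested cytosolic ribosomal protein genes 8 passed, and 17 when adjusted over the list alone, while among 35 translation factors these numbers were 2 and 7. In the same exact test 0 of 73 mitochondrial ribosomal protein genes and 0 of 39 mitosis genes passed either way, with 20 and 6 genes at an unadjusted p under 0.05 in any pair. For the 43 DNA replication genes the counts were 0 and 1, with 8 at an unadjusted p under 0.05. MALAT1, a nuclear long non-coding RNA singled out after its values were seen, had 171, 67.6 and 44.0 CPM in libraries 20, 21 and 23 (exact adjusted p = 1.3e-24 for 23 against 20).

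Library 23 took part in most of these differences. Libraries 21 and 20 differed in 12 genes, 23 and 20 in 42, and 23 and 21 in 31. In the unadjusted exact test 4.36%, 7.97% and 6.55% of genes had p under 0.05. With library 23 left out 8 genes differed, and 33 with library 20 left out. Of the calls, 23 were higher and 19 lower in library 23 than in 20, and 18 higher and 13 lower than in 21. That split depended on the scale: scaled to the spiked RNAs it was 108 higher and 10 lower against library 20 and 167 higher and 5 lower against 21. With median-of-ratios size factors it was 17 and 60 against library 20 and 17 and 44 against 21, and with TMM factors 21 and 28, and 17 and 28. Between libraries 21 and 20 the split was 8 higher and 4 lower in 21, and 1 and 15 on the spike scale. Scaling to the spikes moved the median log2 ratio of all genes with at least 100 pooled counts from 0.01 to 0.10 for library 23 against 20, and from 0.01 to 0.16 against 21. HIST1H4C, MT-CO3, MT-ATP6, MT-ND2 and MT-ND4 kept their direction for library 23 under every scale tried. With genes not reported here left aside, there were 84 calls of a gene in a pair. On the spike scale, which shifts all genes alike, 59 of the 84 stayed past the threshold and 5 turned in sign. With TMM and median-of-ratios factors 0 turned and 81 and 76 stayed. The mean dispersion index, which is 1 for counting error alone, was 1.02 for genes with up to 10 pooled counts and 7.75 for the 71 genes above 10000. The medians were lower, at 0.945 and 2.89, and for genes with 100 to 1000 counts the median was 0.895. Counting error alone gives a median below 1, so a median under 1 does not show an absence of excess spread. The edgeR common coefficient of biological variation between libraries was 0.0537 over 8163 genes, 0.0260 without library 23, and 0.182 from DESeq2 (square root of the median dispersion over genes). Across 11424 genes, which are not independent replicates, the Pearson correlation of log2(CPM + 1) between pairs of libraries was 0.971 to 0.972 and the Spearman correlation 0.967 to 0.968.

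**Figure D3:**
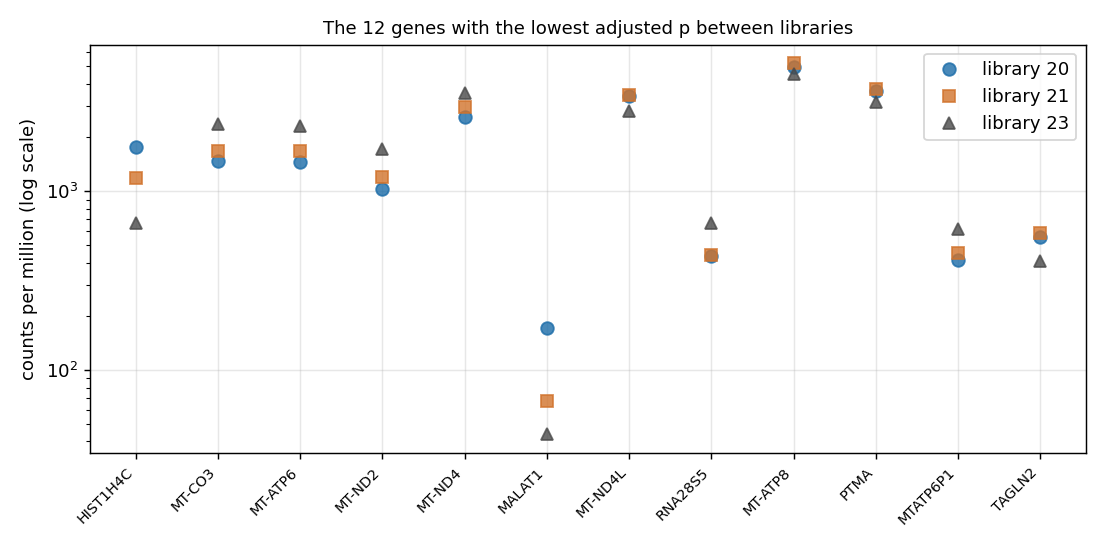
CPM (y axis, log scale) of the 12 genes with the lowest adjusted p between libraries, with 1 point per library. HIST1H4C and MALAT1 were highest in library 20, while MT-CO3 reached 2375 CPM in library 23 against 1479 in library 20.

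The spiked RNAs, a set of synthetic polyadenylated transcripts in known ratios, followed their nominal amounts less than proportionally. Over 50 spikes on a ladder of 13 halving steps, the slope of log2 count on log2 nominal amount was 0.878 ± 0.0015 (SD, n = 3 libraries), with a Pearson correlation of 0.970 ± 0.00025 and a Spearman correlation of 0.964 ± 0.0045 across spikes, which are not independent replicates. Over the 9 spikes of the upper 5 steps the slope was 0.560 ± 0.0065. The most counted spikes were ERCC-00074 at 11141 ± 340, ERCC-00002 at 7661 ± 252 and ERCC-00130 at 6460 ± 297 counts, although the nominal amount of ERCC-00130 is the highest of the ladder. Counts equalled 1.11% ± 0.051 of the nominal molecules for ERCC-00130 and 4.41% ± 0.22 for the 24 spikes 5 to 9 steps down, and 2.77% ± 0.094 of all spike molecules. Between libraries, 0 of 57 spikes differed (exact binomial test, adjusted), and 8 of 171 unadjusted tests had p under 0.05. With 20000 spike molecules per cell and equal capture assumed, endogenous counts came to 523506 ± 26798 molecules per cell (SD, n = 3). The spikes 5 to 9 steps down, a reference chosen after the data were seen, gave 328738 ± 13591.

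**Figure D4:**
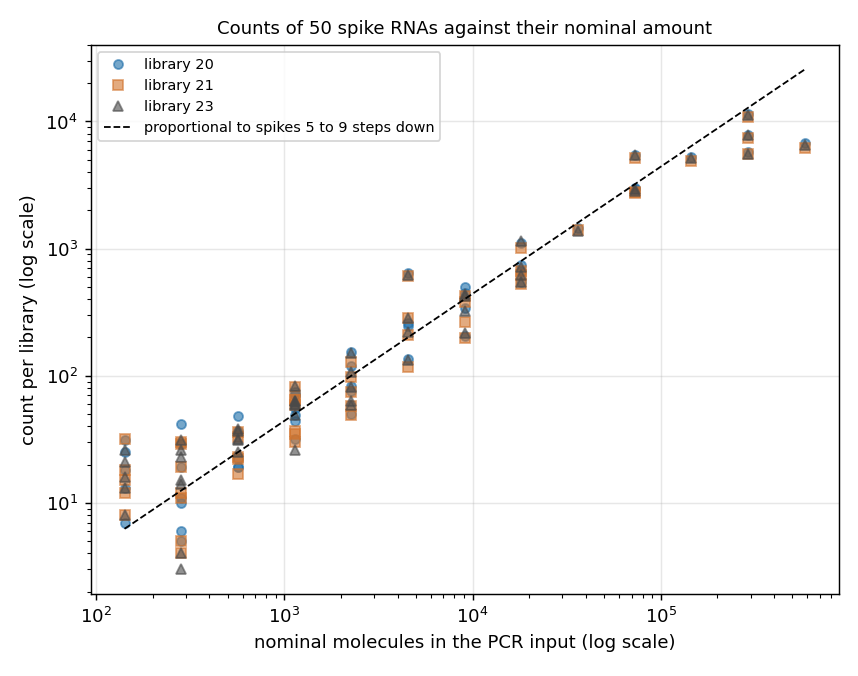
Counts of 50 spiked RNAs (y axis, log scale, 1 point per spike and library) against their nominal molecules in the PCR input (x axis, log scale). The dashed line is proportional to the spikes 5 to 9 steps below the top; the most abundant spike, ERCC-00130, lies below it at 6460 counts on average.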

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

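Among the alternatives below, those using the spikes 5 or more or 5 to 9 steps down, the removal of the GC trend and of the most counted list members were chosen after the result was seen. No paired analysis was possible because the series has 1 group. The number of genes detected in all libraries stayed within 1.5 times its value under every alternative tried, from 9824 with a minimum of 5 counts to 13496 without library 21. Of 43 contrasts 35 kept their direction and side of the threshold in every alternative. Using list medians in place of sums turned 2 of them: the nuclear respiratory chain list over mitochondrially encoded proteins went from 0.25 to -2.37 and DNA replication over mitosis from -0.02 to 0.60. The first was also lost when any library was left out, with limma adjusted p from 0.053 to 0.065. Without the most counted member of the first list, mesenchymal over epithelial markers turned from 1.39 to -0.38, because VIM was removed, and replication-independent over replication-dependent histones lost its call. For these and the values that follow the cause was not tested unless given. Genes differing between libraries numbered 60, 110 with median-of-ratios size factors (53 shared), 232 on the spike scale (48 shared), 76 with TMM factors, and 70 with the GC trend removed (49 shared). Leaving out a library gave 8 (without library 23) to 57, from fewer pairs tested. The coefficient of variation of 0.0537 was 0.182 from DESeq2 (square root of the median dispersion over genes) and 0.0260 (without library 23) to 0.0688 when leaving out a library. Lists with a median below the 2.5th percentile numbered 10, and 2 when only listed members entered, since unlisted members count as 0. The spike slope of 0.878 was 0.873 with a pseudocount of 1, 0.847 for spikes with a mean count of at least 10 and 0.857 for those 5 or more steps down, with Pearson correlations of 0.970, 0.974 and 0.928. Molecules per cell went from 523506 to 560329 without the most counted spike and to 328738 with the spikes 5 to 9 steps down. Among list medians, 164 values stayed within 1 SD and 30 moved. Depth limits single genes: the pair test recovered 43.5% of simulated 1.5-fold changes.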

Other observations

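All tests of explanations here, except the one on shared exons, were chosen after the result was seen, as were the HOX genes. HOX genes encode the transcription factors that set position along the body axis, and 34 of the 39 human HOX genes were listed in the table, 16 of them at 10 CPM or more. Summed counts centred on the middle and posterior groups. The 10 listed genes of groups 9 to 11 summed to 246 ± 20.7 CPM (SD, n = 3 libraries) and the 11 of groups 5 to 8 to 179 ± 11.1 CPM. The 4 listed genes of groups 12 to 13 summed to 78.8 ± 4.38 CPM and the 9 of the anterior groups 1 to 4 to 51.3 ± 12.99 CPM. These are sums over unequal numbers of genes, not levels per gene. The highest were HOXA10 at 64.3 ± 9.58 CPM, HOXB6 at 50.05 ± 10.3 CPM, HOXA9 at 49.1 ± 2.33 CPM, HOXA5 at 48.7 ± 4.38 CPM and HOXD13 at 44.6 ± 0.55 CPM. All 11 HOXA genes were listed, and 7 of 9 in HOXC and in HOXD. HOX genes overlap antisense RNAs, and the use of strand in counting is not known, so single values are uncertain.

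The most abundant spikes were counted lower than their nominal amount predicts: the upper 2 steps lay at a median log2 of -0.99 against proportional counts. Among the 41 spikes 5 or more steps down the slope was 0.857, so a less than proportional response was not confined to the top. The test of saturation below covers the upper 2 steps only. Saturation of identifiers with 4 N and 4 H bases as the whole cause would leave the 4 spikes of those steps near their predicted counts; they lay at a median log2 of -0.56 from them, with bounds of -1.14 to 0.03 from the spread of single spikes, which leaves it open. A loss of counts at high level in the deeper library remains possible, and may be small. The median shift over the 3 pairs was -0.0214 in log2 for genes above 10000 counts, beyond 2 standard errors in 2 pairs, and the third pair (-0.0046, standard error 0.011) differed least in depth. The shifts were -0.0214, -0.0395 and -0.0046 for library 20 to 21, 23 to 21 and 23 to 20. Saturation of identifiers with 4 N and 4 H bases would give -0.0171, -0.0254 and -0.0082, so saturation stays open here too. No biological explanation was tested, since the design gives none for spikes.

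Genes differed between library 23 and the others beyond counting error. A trend with transcript GC content existed, at 0.055 in log2 per 10 percentage points of GC against at most 0.011 in 1000 simulated tables. After its removal 46 of the 57 genes (80.7%) stayed past the threshold. Mitochondrially encoded genes and genes of unknown GC content took no correction, so their calls were not tested by it. Of the 47 genes not encoded by the mitochondrial genome, 45 with known GC content, 36 stayed. For these genes GC content as the whole cause is argued against. A different share of S-phase cells was tested through HIST1H4C. Of 14 tested replication-dependent histone genes it was the only 1 past the threshold (exact test), so the list as a whole did not show its fall. Next by mean CPM, HIST1H2BK had 73.2, 83.4 and 88.6 CPM in libraries 20, 21 and 23. HIST1H1C had 10.2, 14.3 and 12.3 CPM and HIST1H3B 16.3, 6.76 and 9.71 CPM, both on few counts. The DNA replication list had a median log2 ratio of 0.047 (standard error 0.030) where HIST1H4C had -1.15, so the list as a set did not fall with it. This does not decide the question, since how far the list would move with the share of S-phase cells is not known here. CLSPN, an S-phase checkpoint gene outside the list, had 65.7, 50.3 and 29.8 CPM in libraries 20, 21 and 23 (exact adjusted p = 0.0051 for 23 against 20). RNA handling that may differ for RNAs with short or no poly(A) tails, and a difference between cultures, were not tested and stay open. RNA28S5, a ribosomal RNA without a poly(A) tail, was higher in library 23 than in 20 (log2 ratio 0.62, exact adjusted p = 2.8e-14), opposite to HIST1H4C and MALAT1.

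Some members of housekeeping lists are not listed in the table, among them EEF1G, NDUFB8, SDHD, PSMA1 and PSMA2. Of 9 such members 8 have exons that overlap another gene on the same strand in GENCODE v29, against 103 of 414 listed members (Fisher's exact test, 2-sided p = 0.00013). A candidate explanation is that reads in exons shared by 2 genes were not counted. Listed members with such overlap were not lower, however, with a median of 524 CPM against 307 CPM for those without. These medians are of different genes and do not decide it. Rows may also have been left out of the table used here, which was not tested, and no biological explanation was tested.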
